A study of Manduca sexta with 93 samples.

How the data were processed

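The sources are 2 tables of the whole series, both holding raw read counts deposited by the authors: counts per host transcript in 93 libraries, and counts per exon of the *Cotesia congregata* bracovirus (CcBV) annotation in 90 libraries. Libraries were made from single larvae with a 3′ tag kit (QuantSeq 3′ FWD), per the labels' protocols, so that reads come from the ends of polyadenylated transcripts and counts need no length correction. Reads were trimmed with cutadapt 4.1 and checked with FastQC 0.11.5, per the submitters' processing notes. The counts were made with featureCounts 2.0.4, per the file headers, reading the forward strand, per exon and grouped by transcript for the host, against the assembly JHU_Msex_v1.0. The aligner is not given in the sources used here. The counting command allowed neither reads that overlap several features nor reads that map to several places. A read in an exon shared by several transcripts of a gene was therefore not counted, which lowers the counts of the 4222 of 18920 genes with several transcripts, and near-identical gene copies lose reads in the same way. Every host gene singled out in the text as 1 of the largest changes has 1 transcript in the table.

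The host table has 28649 transcripts, of which 27648 were matched by accession and 902 by position to the reference gene table of the same assembly, and 99 (1.33% of all counts) matched no gene. The reference pairs genes with symbols of the form LOC plus a number and gives no product names. None of the 17 gene lists and cell type markers fixed before the data were examined matched any of 18991 symbols and synonyms, so the list tests were not run and no markers of other tissues could be read. By the rule fixed for that case, the text names at most 2 transcripts that rose and 2 that fell per contrast of the factorial design, those with the largest log2 change among those past the threshold with a mean of at least 5 CPM in the higher group. For CcBV it names the 6 genes with the highest mean at 25 °C and the 4 largest changes in each direction, grouped by the viral segment in the identifier. Other descriptions (gene classes, mitochondrial genes, neighbouring genes, overlaps between separate libraries) were chosen after seeing the annotation. The CcBV exons were summed to 115 genes.

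Groups were taken from the sample titles. All 93 columns of the host table and all 90 of the CcBV table were mapped to samples. Replicates are separate larvae. In 346 pairs of libraries of a group the counts differed by more than sampling noise (median chi-square per degree of freedom 166), so no library was counted as a copy of another. Library LAB_40_NP replicate 6 held 0 host counts and entered no fit. Columns for FLD_40_P replicates 2 and 4 and FLD_25_NP replicate 6 were not used here for CcBV, so the FLD viral comparisons rest on 8 libraries at 40 °C and 10 at 25 °C, in place of the 10 and 10 planned, and their permutation test was made exact.

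Host counts were tested with edgeR 4.0.16 (R 4.3.3) by its robust quasi-likelihood test, with TMM factors, the default expression filter by group, group means as the design and Benjamini-Hochberg adjustment at 0.05. LAB and FLD larvae each had a fit of their 4 factorial groups (37 and 40 libraries, 6883 and 6986 transcripts tested, biological coefficient of variation 0.589 and 0.769). All other comparisons used a joint fit of 92 libraries and 14 groups (9372 transcripts, 0.757). Standard errors are those implied by the F statistic. Group means, medians and single-library values of host transcripts in the report are edgeR CPM, per 1000000 counts of the tested transcripts with the total scaled by the TMM factor of the fit. The log2(CPM + 1) values of host transcripts in the closing section, the parasitism score and the pooled bounds and ratios use all host counts of the library without a factor, so the same library has other CPM there. CPM of CcBV, in total and per gene, are per 1000000 host and CcBV counts. CcBV genes with at least 10 counts in at least 5 libraries were tested with edgeR on host library sizes and host TMM factors, so that a change is relative to host mRNA. Viral load is log2 of 1 plus the CcBV counts per 1000000 host and CcBV counts, and was compared with 2-sided exact permutation tests over every split of the libraries. Shares of ribosomal and mitochondrial counts were compared with permutation tests of 100000 resamples. Neighbouring pairs of called genes, consecutive among the tested genes of a chromosome, were compared with 10000 permutations of positions. Intervals for the share of a library are Clopper-Pearson at 95%, and a count of 0 allows up to 3 counts; both cover counting error only, since reads without molecular identifiers are not independent molecules. At the median total 3 counts are under 1 CPM, while in library LAB_25_P replicate 1 they are 317 CPM.

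The fits were tested on simulated counts drawn from the real means and library sizes with 200 changed transcripts. The draws were independent between transcripts and libraries, without outlying larvae or other structure of the samples, so recovery in the real data may be lower. For parasitism at 40 °C in LAB larvae (6772 transcripts) 46.3, 79.1 and 92.4% of changes of 2-, 4- and 8-fold were recovered. For heat in FLD sham larvae (6818 transcripts) 20.9, 67.2 and 81.8% were recovered, and for heat in FLD parasitized larvae (6816 transcripts) 16.4, 68.7 and 78.8%. For the sham at 40 °C (8985 transcripts) the shares were 10.4, 43.3 and 51.5%. For CcBV genes, 50 and 83.3% of 4- and 16-fold changes were recovered in LAB larvae (53 genes) and 66.7 and 100% in FLD larvae (54 genes), with 6 genes per fold.

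Alternatives fixed before the data were examined were DESeq2 1.42.0, relative log expression factors, upper-quartile factors, no filter, a stricter filter (10 counts in 9 libraries), other libraries in the fit, the replicate number as a block, the specimen number as a covariate, and leaving out libraries with under 1/3 of the median total or each LABINFIELD and unmanipulated larva in turn. For CcBV they were other denominators, pseudocounts of 0.1 and 10 CPM, medians, CcBV library sizes, other filters and added LABINFIELD larvae. Upper-quartile factors could be formed only without the low libraries. Alternatives added after seeing the data left out ribosomal RNA genes, summed transcripts per gene, or left out the 2 libraries labelled parasitized with CcBV at background, together or, for viral load, in turn, also for the segment shares, or left out the LAB_40_NP library with the highest mitochondrial share (for mitochondrial genes also that of LAB_40_P) or, for each named host transcript and CcBV gene, the library with the highest CPM. Shares in LABINFIELD larvae were compared with FLD and LAB larvae by exact permutation tests, also without the LABINFIELD library with the highest ribosomal RNA share. Counts of calls were compared with those of 100 splits of the same libraries, or 40 in the joint fit (all 35 for heat in unmanipulated larvae), and for parasitism at 25 °C also by the calls shared with 40 °C in 1 direction. A score of parasitism was the mean, over 149 transcripts called in FLD larvae at 40 °C and tested in LAB larvae, of the log2(CPM + 1) of a LAB library minus that of the other sham larvae at its temperature, with the sign of the FLD change. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 served for the remaining tests and plots.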

Results

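The series measured polyadenylated RNA of the fat body, the insect organ of storage, metabolism and humoral immunity, in larvae of the tobacco hornworm *Manduca sexta*. Third-instar larvae were parasitized by the wasp *Cotesia congregata* (P), injected with Sephadex beads as a sham (NP), or left unmanipulated (NOSHAM). The wasp injects its eggs together with the bracovirus CcBV, whose genes are transcribed in the host. Some hours later the larvae spent 24 h at 25 or 40 °C and then 24 h at 25 °C, so heat is compared after a recovery period. Laboratory larvae (LAB) and larvae of a field population from North Carolina (FLD) were run at different times, and a few laboratory larvae were run beside the field larvae (LABINFIELD). The 14 groups held 10 (LAB_25_NP), 9 (LAB_25_P), 10 (LAB_40_NP) and 9 (LAB_40_P) libraries, 10 in each of the 4 FLD groups, 2 in each of the 4 LABINFIELD groups, 4 in LAB_25_NOSHAM and 3 in LAB_40_NOSHAM. Each library came from 1 larva. Library LAB_40_NP replicate 6 held 0 host counts, which left 92 libraries and 9 in its group. Their host totals ran from 1283 to 13527808 counts with a median of 3929848, and the lowest totals were 1283 in FLD_40_NP replicate 1 and 9450 in LAB_25_P replicate 1, while every other library had at least 1469736. Ribosomal RNA genes took from 3.38 to 47.2% of the host counts of a library.

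Bracovirus counts separated parasitized from other larvae in both populations. The mean was 9914 ± 9382 counts per 1000000 (CPM, SD, n = 9) in LAB_25_P, 4461 ± 3054 (n = 9) in LAB_40_P, 8960 ± 5698 (n = 10) in FLD_25_P and 3897 ± 2027 (n = 8) in FLD_40_P. The background, measured the same way, had group means of 14.8 to 41.7 CPM in sham and unmanipulated larvae: 48 of 49 such libraries held CcBV counts, with a median of 18.3 and a maximum of 140 CPM. Every FLD parasitized library lay above every FLD sham library, 10 of 10 at 25 °C and 8 of 8 at 40 °C. In LAB larvae 8 of 9 did so at each temperature. The library labelled LAB_25_P replicate 8 held 19 CPM (Clopper-Pearson 95% interval 15.1 to 23.6) and the library labelled LAB_40_P replicate 8 held 21.7 CPM (17.2 to 27.1), so both lay at the background although their labels say parasitized. Both stayed in their groups in all values below unless stated.

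**Figure D1:**
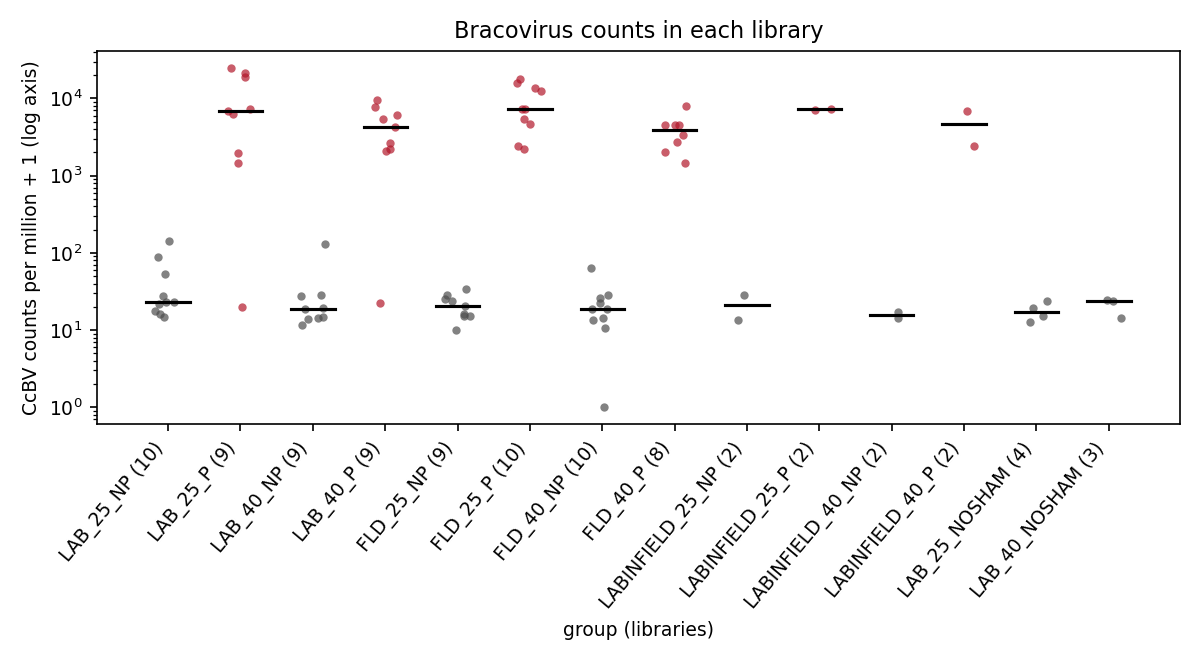
CcBV CPM plus 1 on a log axis, for each library (points; red, parasitized; grey, sham or unmanipulated) by group, with the group median as a bar. Parasitized libraries lie above the highest background library of 140 CPM, except the library labelled LAB_25_P replicate 8 at 19 CPM and the library labelled LAB_40_P replicate 8 at 21.7 CPM.

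The study asked whether a heat shock changes the interaction of the host with this virus. Most CcBV genes that differed after heat were lower relative to host counts, and 1 gene, CcBV_18.2, passed as higher in each population, a call that in LAB larvae ended without 1 library. In FLD larvae 20 of 56 tested CcBV genes differed, 1 higher and 19 lower, and in LAB larvae 10 of 55 differed, 1 higher and 9 lower (edgeR, Benjamini-Hochberg). The counts depended on the fit: 1 fit of the 4 parasitized groups gave 13 in FLD larvae, 2 higher and 11 lower, and 19 in LAB larvae, 2 higher and 17 lower. This turned the order of the populations. In LAB larvae DESeq2 gave 20 and the specimen number as a covariate 6. Without LAB_25_P replicate 9 the LAB count was 5, and without LAB_25_P replicate 2 or LAB_40_P replicate 1 it was 6, choices made after seeing the data. CcBV_18.2 rose from 80.7 ± 68.7 CPM (n = 9) to 717 ± 1235 CPM (n = 9) in LAB larvae, a log2 change of 2.83 ± 1.06 (SE, edgeR adjusted p = 0.0435), and from 96.9 ± 93.5 CPM (n = 10) to 716 ± 499 CPM (n = 8) in FLD larvae, a log2 change of 2.82 ± 0.66 (edgeR adjusted p = 0.00405). The LAB_40_P median was 262 CPM and the maximum 3945. Without that library, LAB_40_P replicate 1, the mean was 314 ± 265 CPM (n = 8) and the log2 change 1.69 ± 1.05, which no longer passed (edgeR adjusted p = 0.246). In FLD larvae it was 2.60 without the highest library (edgeR adjusted p = 0.0061). The 9 genes lower in both populations were CcBV_1-13.1, CcBV_19.5, CcBV_2.2, CcBV_30.6, CcBV_5.1, CcBV_5.3, CcBV_6.1, CcBV_6.2 and CcBV_9.4, against 3.17 expected from independent lists. CcBV_1-13.1 went from 118 ± 157 to 11 ± 9.94 CPM in LAB larvae (log2 −3.56 ± 1.06, edgeR adjusted p = 0.00957) and from 213 ± 284 to 9.29 ± 7.21 CPM in FLD larvae (log2 −4.66 ± 1.03, edgeR adjusted p = 0.00362).

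In LAB larvae CcBV_5.1 had the most negative log2 change of the genes that passed, −3.82 ± 1.1, followed by CcBV_6.1 with −3.67 ± 1.07, each with an edgeR adjusted p of 0.00957. In both populations CcBV_19.5 was lower, with −3.40 ± 1.09 in LAB and −3.07 ± 0.77 in FLD larvae. Without LAB_25_P replicate 9 at 2033 CPM, beside a median of 178, the LAB change was −2.77 and no longer passed (edgeR adjusted p = 0.0801). In FLD larvae CcBV_30.6 had −3.46 ± 0.90 and CcBV_9.4 had −3.06 ± 0.76, both with an edgeR adjusted p of 0.00413. The 6 genes with the highest mean at 25 °C made up 60.2% of CcBV counts in LAB larvae (CcBV_5.5, CcBV_2.5, CcBV_30.1, CcBV_22.4, CcBV_2-13.1 and CcBV_19.5) and 56.9% in FLD larvae (CcBV_30.1, CcBV_2.5, CcBV_5.5, CcBV_2-13.1, CcBV_5.2 and CcBV_19.5). CcBV_30.1 had −1.95 in FLD larvae (edgeR adjusted p = 0.0184) and −1.61 without FLD_25_P replicate 5 (edgeR adjusted p = 0.0515). CcBV_5.5, at 1426 ± 1134 CPM (n = 9) in LAB_25_P and 828 ± 396 CPM (n = 10) in FLD_25_P, had a log2 change of −2.30 ± 1.04 in LAB larvae (edgeR adjusted p = 0.0877) and −2.0 ± 0.59 in FLD larvae (edgeR adjusted p = 0.00934). Across the 54 genes tested in both populations the log2 changes had a Pearson r of 0.82 and a Spearman rho of 0.81; this is a correlation across genes, which are not independent replicates. No gene passed the test of a different heat effect in FLD and LAB larvae (0 of 60 in edgeR, 0 with an unadjusted p under the threshold, 0 with DESeq2). The standard error of that difference was at least 1.02 on the log2 scale and its largest estimate 1.91 (CcBV_4.1a), so differences of that size were not excluded. These directions are relative to host mRNA: with library sizes and factors from CcBV counts alone, 12 genes differed in FLD larvae, 9 higher and 3 lower, and 15 in LAB larvae, 7 higher and 8 lower. Without the 2 libraries labelled parasitized at background, a choice made after seeing the data, 24 genes differed in LAB larvae, 2 higher and 22 lower, and 26 also without library LAB_25_P replicate 1.

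**Figure D2:**
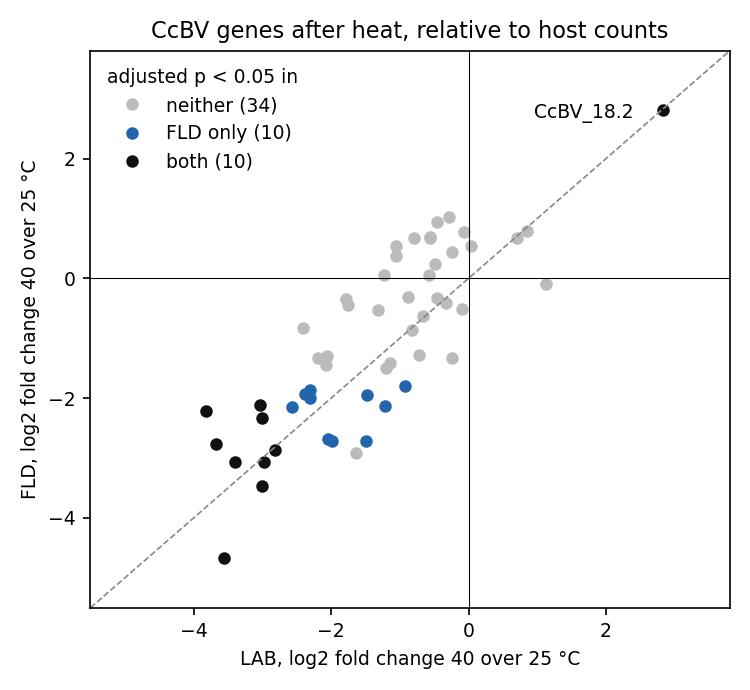
Log2 fold change of each of 54 CcBV genes at 40 over 25 °C, relative to host counts, in LAB (x axis) and FLD (y axis) parasitized larvae; points are genes, coloured by the population in which the adjusted p passed the threshold, and the dashed line marks equal change. CcBV_18.2 lies at 2.83 and 2.82 (LAB 1.69 without LAB_40_P replicate 1), and the 9 other genes that passed in both populations lie below 0 in both.

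The make-up of the viral transcripts changed with heat, described by the viral DNA segment in each gene's identifier. Segment 18 took 3.10 ± 2.81% of CcBV counts at 25 °C and 17.5 ± 14.4% at 40 °C in LAB larvae (n = 9 and 9, exact permutation p = 0.000247, adjusted over 16 segments 0.00395), with 7 of 9 heated libraries above the highest at 25 °C. In FLD larvae it took 1.91 ± 1.23% (n = 10) and 20.4 ± 7.68% (n = 8), with 7 of 8 heated libraries above the highest at 25 °C (exact permutation p = 4.57e-05, adjusted over 15 segments 0.000686). At 40 °C CcBV_18.2 and CcBV_18.1 held most of these counts. Their means were 717 and 316 CPM in LAB and 716 and 135 CPM in FLD larvae. Relative to host counts only CcBV_18.2 passed, 1 of 4 tested genes of the segment in LAB and 1 of 3 in FLD larvae. With CcBV library sizes alone CcBV_18.1 also rose, by 2.14 and 1.94 on the log2 scale (edgeR adjusted p = 0.000437 and 0.0165). Shares are parts of 1 total, so a rise in 1 segment lowers others. Segment 30 rose from 13.7 ± 3.46 to 22.3 ± 5.23% in LAB larvae (n = 9 and 9, adjusted exact permutation p = 0.00757), where FLD larvae had 24.9 ± 10.0 and 22.7 ± 10.9% (adjusted exact permutation p = 0.877). Segment 5 went from 25.3 ± 12.6 to 13 ± 3.10% in LAB larvae (adjusted exact permutation p = 0.0362) and from 20.3 ± 12 to 9.60 ± 3.60% in FLD larvae (adjusted exact permutation p = 0.09). Segments 12 and 3 rose in FLD larvae, from 0.924 ± 0.620 to 2.73 ± 1.61% and from 0.901 ± 0.739 to 2.50 ± 1.39% (n = 10 and 8, adjusted exact permutation p = 0.00206 and 0.026). In LAB larvae they took 1.42 ± 2.28 and 1.44 ± 0.458%, and 1.20 ± 1.18 and 1.49 ± 0.390% (n = 9 and 9, adjusted exact permutation p = 0.996 and 0.622). Without library LAB_25_P replicate 1, a choice made after seeing the data, segment 12 took 0.706 ± 0.826% at 25 °C in LAB larvae (n = 8). Against 1.44% at 40 °C, that rise had an exact permutation p of 0.0386, adjusted 0.124. Segment 3 then took 1.35 ± 1.16% at 25 °C (adjusted exact permutation p = 0.75). These tests are 2-sided, and the difference in share between populations was not tested. Without the 2 LAB libraries at background and library LAB_25_P replicate 1, with its 9450 counts, a choice made after seeing the data, segment 18 took 2.58 ± 0.980% at 25 °C and 19.2 ± 14.4% at 40 °C (n = 7 and 8, adjusted exact permutation p = 0.00249). All 8 heated libraries then lay above the highest at 25 °C, and segments 30 and 5 passed with adjusted exact permutation p of 0.0207 and 0.00249.

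**Figure D3:**
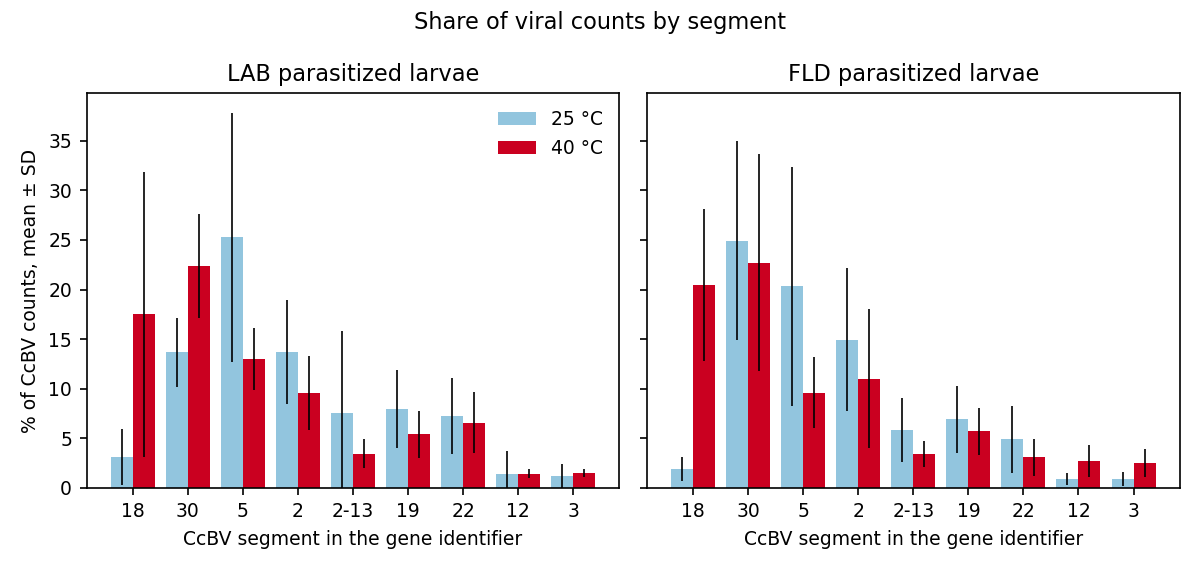
Percent of CcBV counts (mean, bars; SD, error lines) of 9 viral segments in parasitized LAB (n = 9 and 9) and FLD (n = 10 and 8) larvae at 25 and 40 °C. Segment 18 went from 3.10 to 17.5% in LAB and from 1.91 to 20.4% in FLD larvae.

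Total viral load did not pass its test after adjustment, and in FLD larvae this depended on the scaling. On the log2(CPM + 1) scale the 40 °C minus 25 °C difference was −1.05 (SE 0.44) in FLD larvae (n = 8 and 10, exact permutation p = 0.0363, adjusted over the 2 populations 0.0726) and −0.66 (SE 1.38) in LAB larvae (n = 9 and 9, exact permutation p = 0.593, adjusted 0.593). Over the alternatives the FLD exact permutation p ran from 0.0173 to 0.0975. With host sizes scaled by TMM factors the difference was −1.22 (exact permutation p = 0.0173, adjusted 0.0346), and without ribosomal RNA genes −1.12 (exact permutation p = 0.0232, adjusted 0.0464), so both passed. The difference of medians was −0.92 (exact permutation p = 0.0975, adjusted 0.195). In LAB larvae the difference was −0.77 without both libraries at background (exact permutation p = 0.235) and −1.10 also without library LAB_25_P replicate 1 (exact permutation p = 0.0771), alternatives chosen after seeing the data. Leaving out 1 of the 2 at a time moved it apart, to 0.18 without the library labelled LAB_40_P replicate 8 (exact permutation p = 0.928) and to −1.61 without the library labelled LAB_25_P replicate 8 (exact permutation p = 0.133).

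Parasitized and sham larvae differed in many host transcripts at 40 °C in both populations. In LAB larvae at 40 °C 463 of 6883 tested transcripts differed between parasitized and sham larvae, 180 higher and 283 lower, and in FLD larvae 155 of 6986 did, 48 higher and 107 lower (edgeR, Benjamini-Hochberg). The populations overlapped in 84 of the 6546 transcripts tested in both, 17 higher in both and 67 lower in both, with 0 in opposite directions, where independent lists would share 1.28 and 4.24. These lists come from separate libraries. Of 149 FLD calls 143 had the same sign in LAB larvae, and of 450 LAB calls 396 had the same sign in FLD larvae. Across all 6546 transcripts the log2 changes had a Pearson r of 0.53 and a Spearman rho of 0.41, over transcripts that are not independent replicates. Without the 2 libraries labelled parasitized at background and library LAB_25_P replicate 1, the LAB count was 757, 343 higher and 414 lower. The order of the populations depended on the fit: with all 14 groups in it the LAB count was 235, 78 higher and 157 lower, and the FLD count 440, 179 higher and 261 lower. DESeq2 gave 288 in FLD larvae, 95 higher and 193 lower.

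LOC115456038, a protein-coding gene on an unplaced scaffold (8498 to 9196, assembly JHU_Msex_v1.0 as for all coordinates here), rose in parasitized LAB larvae at 40 °C from 3.46 ± 3.86 to 106 ± 110 CPM (n = 9 and 9), a log2 change of 4.98 ± 0.70 (edgeR adjusted p = 6.12e-05), and had 3.98 in FLD larvae (edgeR adjusted p = 0.0336). LOC115448789 on chromosome 4 (1013008 to 1019076) rose from 39.8 ± 28.7 to 941 ± 1247 CPM in LAB larvae, a log2 change of 4.57 ± 0.89 (edgeR adjusted p = 0.00114), and had 1.97 in FLD larvae (edgeR adjusted p = 0.089). LOC115453835 on chromosome 26 (4864780 to 4866061) was lower in LAB larvae, at 17.2 ± 7.47 CPM in sham and 0.240 ± 0.303 CPM in parasitized larvae (log2 −5.93 ± 0.68, edgeR adjusted p = 1.48e-06), and had −2.65 in FLD larvae (edgeR adjusted p = 0.0648). LOC115450134 on chromosome 25 (1390742 to 1392177) had −6.0 ± 1.36 in LAB larvae (edgeR adjusted p = 0.00477), but its sham mean of 115 ± 322 CPM (n = 9) rests on 1 library at 974 CPM beside a median of 3.38. Without that library, LAB_40_NP replicate 9, the log2 change was −2.10 and no longer passed (edgeR adjusted p = 0.223). In FLD larvae it was −1.21 (edgeR adjusted p = 0.645).

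In FLD larvae at 40 °C LOC115440293 on chromosome 18 (15042573 to 15043593) rose with parasitism from 1.28 ± 1.34 to 67.2 ± 44.2 CPM (n = 10 and 10), a log2 change of 5.49 ± 0.97 (edgeR adjusted p = 0.000685), and it also passed in LAB larvae with 2.74 (edgeR adjusted p = 0.00909). LOC115450804 on chromosome 9 (7463630 to 7466534) was lower, with 395 ± 674 CPM in sham and 3.78 ± 3.08 CPM in parasitized larvae (log2 −6.74 ± 1.05, edgeR adjusted p = 0.000164), and had −4.39 in LAB larvae (edgeR adjusted p = 0.027). Its sham median was 167 CPM, and without library FLD_40_NP replicate 10 at 2226 CPM the mean was 192 and the log2 change −5.73 (edgeR adjusted p = 0.000276). LOC115454115 on chromosome 21 (6694781 to 6699119) held 435 counts in the FLD sham larvae and 0 in the 10 parasitized larvae (edgeR adjusted p = 0.00159); against a floor of 3 counts over the group it was at least 204-fold lower. The bound was 112-fold without library FLD_40_NP replicate 8 at 68 CPM beside a median of 3.75. LOC115447475 on chromosome 9 (4292808 to 4300304) held 306 counts in parasitized and 3 in sham larvae, a log2 change of 5.88 ± 1.63 (edgeR adjusted p = 0.0447). The pooled ratio was 72.6 with a counting interval of 24.6 to 354. That interval covers counting error only, and 6 of 10 parasitized libraries held any count of this gene. Without library FLD_40_P replicate 7 at 37.6 CPM the ratio was 51.7 and the gene no longer passed (edgeR adjusted p = 0.0947).

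**Figure D4:**
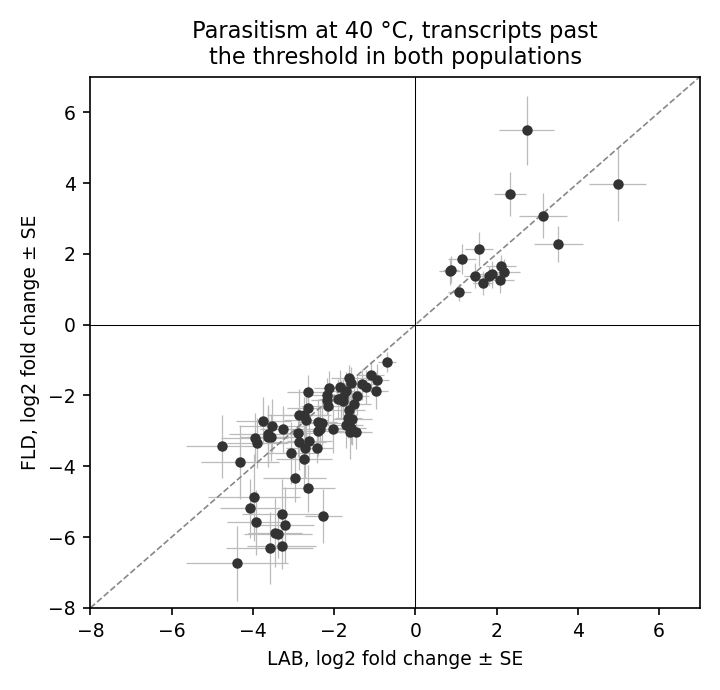
Log2 fold change, parasitized over sham at 40 °C, of the 84 host transcripts that passed the threshold in both populations, LAB on the x axis and FLD on the y axis, with standard errors as lines and equal change as a dashed line. The 17 transcripts higher in both lie in the upper right and the 67 lower in both in the lower left.

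Genes that changed with parasitism at 40 °C followed each other in the chromosomal order of the tested genes more often than under permuted positions. Neighbours and runs, here and below, are consecutive among tested genes, 6316 in LAB and 6412 in FLD larvae of 18920 genes in the table, so untested genes can lie between them. Among 438 called LAB genes with a position there were 41 pairs of neighbours changed in the same direction, where permuted positions gave a mean of 15.8 (permutation p = 1e-04, the smallest that the 10000 permutations can give). Among 146 FLD genes there were 14 such pairs against 1.85 (permutation p = 1e-04). An excess of pairs was seen in every other contrast tested this way, so it is not particular to parasitism. Heat in LAB sham larvae had 10 pairs against 2.73 (permutation p = 5e-04), and FLD minus LAB across runs 850 against 700 (permutation p = 1e-04). Runs of 3 lower genes lay on chromosome 4 (10828840 to 10891132, log2 changes of −6.40 to −5.65) in FLD larvae, and on chromosomes 2 (7540398 to 7599295), 11 (10231389 to 10768966), 13 (10417097 to 10453569) and 25 (11682501 to 11709396) in LAB larvae. A run of 3 higher genes lay on chromosome 10 (7952337 to 9238195) in LAB larvae. Neighbouring genes can be copies of each other, and reads that fit several places were left out of the counts, so the split of reads within such a run is uncertain. By class, 2 of 5 tested transfer RNA genes were higher in parasitized LAB larvae at 40 °C. In FLD larvae none of 5 passed, with log2 changes of −2.44 to 0.57 and a median of −0.29. Transfer RNA rows held 28418 host counts in all (0.0079%), and the kit reads polyadenylated ends. These calls therefore need not be changes in transfer RNA, and the source of the reads was not tested.

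How many host transcripts differed with parasitism at 25 °C depended on the fit. In LAB larvae 6 of 6883 passed, 1 higher and 5 lower, and in FLD larvae 17 of 6986 passed, 4 higher and 13 lower (edgeR). LOC119190794, a long noncoding RNA gene on chromosome 26 (1453459 to 1455158), rose in LAB larvae from 6.85 ± 2.33 (n = 10) to 21.8 ± 12.5 CPM (n = 9), a log2 change of 1.81 ± 0.27 (edgeR adjusted p = 0.000473). LOC115453672 on chromosome 18 (6692013 to 6693749) went from 105 ± 115 to 1.14 ± 1.91 CPM (log2 −6.31 ± 1.31, edgeR adjusted p = 0.0297). LOC115441721 on chromosome 25 (4975731 to 4980914) had −4.41 ± 0.78 in LAB larvae (edgeR adjusted p = 0.00532) and 4.63 in FLD larvae (edgeR adjusted p = 0.216), with an LAB sham median of 8.31 CPM. Without LAB_25_NP replicate 6 at 286 CPM the log2 change was −3.68 (edgeR adjusted p = 0.0186). In FLD larvae LOC119191419 on an unplaced scaffold (17718 to 27917) rose from 2.41 ± 2.93 to 83 ± 92.5 CPM (n = 10 and 10; log2 5.06 ± 1.06, edgeR adjusted p = 0.0173), and LOC115456025 on an unplaced scaffold (4964 to 5958) went from 529 ± 485 to 18.7 ± 23.4 CPM (log2 −4.82 ± 1.0, edgeR adjusted p = 0.0164). LOC115441320 on chromosome 19 (2119657 to 2136794) had −5.62 ± 0.96 (edgeR adjusted p = 0.00132). LOC115441792 on chromosome 10 (1855400 to 1867995) had 5.84 ± 1.31 (edgeR adjusted p = 0.0318), with 1 library at 1650 CPM beside a median of 2.19. Without that library, FLD_25_P replicate 10, it had −0.05 (edgeR adjusted p = 0.998). In the other population LOC119190794 had 1.33, LOC115453672 −1.73, LOC119191419 0.25 and LOC115456025 −3.99, none of which passed (edgeR adjusted p from 0.265 to 0.988). Across the 6546 transcripts tested in both populations the log2 changes had a Pearson r of −0.13 and a Spearman rho of −0.14, and no call was shared. Of 6 LAB calls 3 had the same sign in FLD larvae, and of 15 FLD calls 15 did in LAB larvae. Of the 17 transcripts called in FLD larvae at 25 °C, 13 were also lower at 40 °C, in separate libraries, where independent lists would share 0.199. Both lists come from the FLD fit with its shared estimate of spread, so they are not fully independent. Without the 2 libraries labelled parasitized at background, the LAB count at 25 °C was 30, 5 higher and 25 lower, and 27 also without library LAB_25_P replicate 1. With no filter the FLD count was 26. With all 14 groups in the fit the counts were 0 in LAB larvae (edgeR; 483 with an unadjusted p under 0.05 in the LAB fit) and 195 in FLD larvae, 117 higher and 78 lower. DESeq2 gave 53 and 74, the latter 42 higher and 32 lower.

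**Figure D5:**
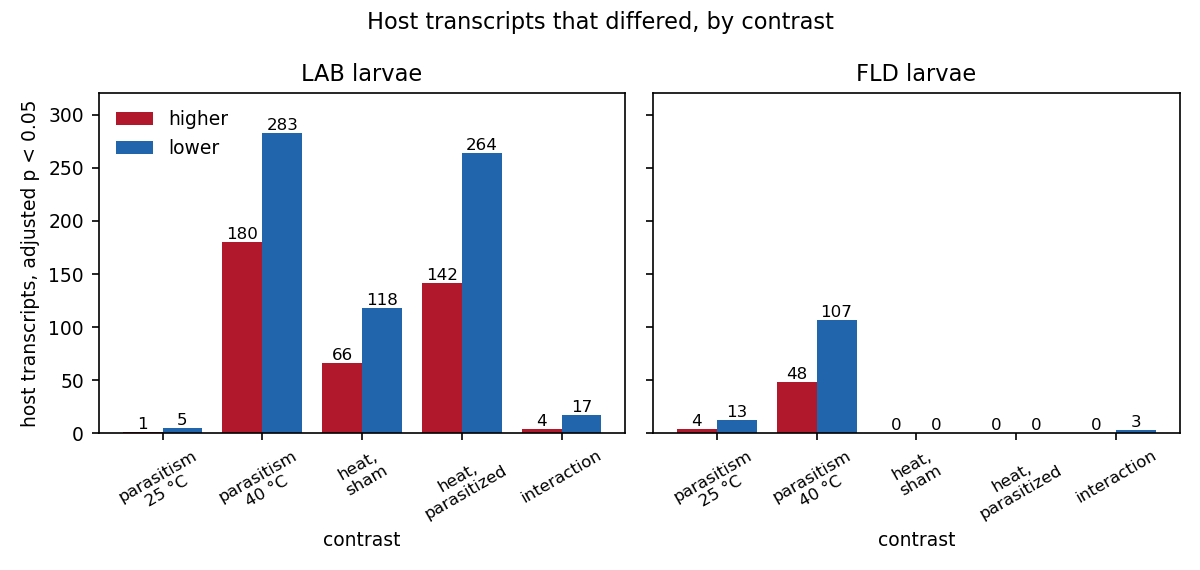
Number of host transcripts higher (red) and lower (blue) with an adjusted p under 0.05 in each contrast of the factorial design, in LAB larvae (left) and FLD larvae (right). Parasitism at 40 °C gave 180 higher and 283 lower in LAB and 48 higher and 107 lower in FLD larvae, and both heat contrasts gave 0 in FLD larvae, where a fit of all 14 groups gave 67 in sham and 363 in parasitized larvae.

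Whether the effect of parasitism depended on temperature was tested as an interaction. In LAB larvae 21 transcripts passed, 4 higher and 17 lower, and in FLD larvae 3 passed, all 3 lower (edgeR). LOC115456039 on chromosome 3 (1355761 to 1356534) reached 91.9 ± 64 CPM in LAB_40_P, against 10.4 ± 7.58 in LAB_40_NP, 1.18 ± 1.48 in LAB_25_P and 2.06 ± 1.32 in LAB_25_NP (interaction log2 3.72 ± 0.81, edgeR adjusted p = 0.0287). LOC115448936 on chromosome 25 (15122052 to 15122860) had 3.06 ± 0.62 (edgeR adjusted p = 0.0209). LOC115445497 on chromosome 13 (5137933 to 5140541) was at 0.654 ± 0.757 CPM in LAB_40_P against 16.8 ± 10.2 in LAB_40_NP, and at 9.11 ± 10.0 in LAB_25_P against 4.35 ± 4.53 in LAB_25_NP (interaction log2 −6.02 ± 1.1, edgeR adjusted p = 0.0149). LOC115449158 on an unplaced scaffold (4756 to 11406) had −5.72 ± 1.26 (edgeR adjusted p = 0.0287). It was at 2.55 ± 6.30 CPM in LAB_40_P against 48.5 ± 44 in LAB_40_NP, and at 30.5 ± 56.3 in LAB_25_P against 12.9 ± 16.6 in LAB_25_NP. The LAB_40_P median was 0.318 with 19.3 in the library at background, and the LAB_25_P median was 15.8 with a maximum of 179. In FLD larvae LOC115446822 on chromosome 13 (9757272 to 9762475) was at 24.0 ± 12.1 CPM in FLD_40_P against 261 ± 139 in FLD_40_NP, and at 94 ± 73.8 in FLD_25_P against 148 ± 67.3 in FLD_25_NP (interaction log2 −2.82 ± 0.57, edgeR adjusted p = 0.033). LOC115451181 on chromosome 8 (10066805 to 10070573) had −3.39 ± 0.62 (edgeR adjusted p = 0.0185). In the other population none of these 6 passed (edgeR adjusted p from 0.136 to 0.999). The FLD interaction was −0.49 for LOC115456039, −0.0016 for LOC115448936, −1.49 for LOC115445497 and −4.81 for LOC115449158, and the LAB interaction was −1.23 for LOC115451181 and −1.56 for LOC115446822. Without the highest library of the highest group, a choice made after seeing the data, 4 of these 6 calls missed the threshold while their log2 changes moved by less than their standard errors. LOC115456039 had 3.55 (edgeR adjusted p = 0.0542), LOC115449158 −5.35 (0.0528), LOC115451181 −3.13 (0.052) and LOC115446822 −2.63 (0.0693). Without the 2 libraries labelled parasitized at background the LAB interaction count was 154, 26 higher and 128 lower, and it held all 21 of the reported transcripts. Without library LAB_25_P replicate 1, with its 9450 counts, it was 32, and without all 3 it was 166. The specimen number as a covariate gave 33 in LAB and 1 in FLD larvae, no filter gave 13 and 5, and upper-quartile factors without the low libraries gave 1 in FLD larvae. With all 14 groups in the fit 8 transcripts passed in LAB larvae, 4 higher and 4 lower, and 184 in FLD larvae, 68 higher and 116 lower. DESeq2 gave 91, 27 higher and 64 lower, and 66, 18 higher and 48 lower.

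After 24 h of recovery, heated and unheated LAB larvae still differed in host transcripts. In LAB sham larvae 184 transcripts differed, 66 higher and 118 lower, and in LAB parasitized larvae 406 differed, 142 higher and 264 lower (edgeR). DESeq2 gave 351, 118 higher and 233 lower, and 677, 278 higher and 399 lower. These contrasts use separate libraries and shared 55 transcripts, 12 higher and 43 lower in both, where independent lists would share 1.36 and 4.53. Both come from the LAB fit with its shared estimate of spread, so the lists are not fully independent. In FLD larvae 0 transcripts passed in sham larvae (614 with an unadjusted p under 0.05, 33 with DESeq2) and 0 in parasitized larvae (806 unadjusted, 112 with DESeq2, smallest edgeR adjusted p = 0.0519). In the latter, relative log expression factors gave 14, no filter 27, the stricter filter 26 and leaving out ribosomal RNA genes 29. Of the 396 LAB calls in parasitized larvae tested in both, 325 had the same sign in FLD larvae, while 78 of 173 did in sham larvae. The difference in heat effect between populations passed for 31 transcripts in sham larvae, 13 higher and 18 lower in FLD larvae, and for 4 in parasitized larvae, 1 higher and 3 lower (edgeR, all libraries in the fit). With only the compared groups in the fit the counts were 18, 11 higher and 7 lower, and 1, and DESeq2 gave 120, 75 higher and 45 lower, and 24, 10 higher and 14 lower. The specimen number as a covariate gave 14 and 0 (edgeR; 675 with an unadjusted p under 0.05 for the latter). In parasitized larvae the difference passed for 7 under relative log expression factors or without the low libraries, for 10 without the 2 libraries at background and for 16 without both kinds, which gave 20 in sham larvae. With all 14 groups in the fit the heat counts were 110 in LAB and 67 in FLD sham larvae, and 171 in LAB and 363 in FLD parasitized larvae, where the order of the populations turned.

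Among heat-responsive genes of LAB sham larvae, 5 neighbouring genes on chromosome 23 (2232018 to 2288478) were higher by 3.64 to 7.15 on the log2 scale. They include the long noncoding RNA genes LOC115443781 (2265268 to 2265767), which rose from 0.396 ± 0.652 (n = 10) to 65.2 ± 116 CPM (n = 9; log2 7.15 ± 1.42, edgeR adjusted p = 0.00372), and LOC115443801 (2232018 to 2232509), with 6.88 ± 1.34 (edgeR adjusted p = 0.00357). LOC115439806 on chromosome 18 (9939804 to 9953880) had −7.11 ± 1.25 (edgeR adjusted p = 0.00181) and LOC115452672 on chromosome 11 (13679908 to 13692636) had −6.80 ± 1.22 (edgeR adjusted p = 0.00194). A few libraries carried these means: in the higher group LOC115443781 had a median of 12.3 and a maximum of 346 CPM, LOC115443801 of 7.33 and 161, LOC115439806 of 7.23 and 456, and LOC115452672 of 60 and 913. Without that 1 library the calls held (edgeR adjusted p from 0.00397 to 0.0111), with 6.03 for LOC115443781 and 6.26 for LOC115443801, whose mean went from 42.2 to 27.3 CPM without LAB_40_NP replicate 2. In FLD sham larvae none of these 4 passed, with 1.49 for LOC115443781, 0.22 for LOC115443801, −2.40 for LOC115439806 and 0.028 for LOC115452672 (edgeR adjusted p from 0.691 to 0.999). A run of 3 genes on chromosome 25 (1460342 to 1476180) was lower after heat in LAB sham larvae, by −6.0 to −4.10, and in LAB parasitized larvae, by −5.15 to −3.96. In parasitized LAB larvae LOC115456038, measured in the same LAB_40_P libraries as above, rose from 0.373 ± 0.358 to 106 ± 110 CPM (n = 9 and 9; log2 7.92 ± 0.89, edgeR adjusted p = 3.6e-07). LOC115456026 on chromosome 3 (4624325 to 4625106) held 1 count at 25 °C and 226 at 40 °C, a log2 change of 6.60 ± 0.75 (edgeR adjusted p = 3.6e-07). Its pooled ratio was 233 and rests on that 1 count. The counting interval of 41.4 to 9237 covers counting error only. LOC115447244 on chromosome 5 (7417773 to 7419682) had −6.09 ± 1.09 (edgeR adjusted p = 0.000805) with a median of 5.43 and a maximum of 223 CPM at 25 °C, and LOC115454425 on chromosome 17 (6480606 to 6485053) had −6.50 ± 1.52 (edgeR adjusted p = 0.00737) with 1 library at 83.3 CPM beside a median of 0.553 at 25 °C. Without the highest library at 25 °C these had −4.73 and −4.99 (edgeR adjusted p = 0.0025 and 0.0409). In FLD parasitized larvae none of the 4 passed, with 5.38 for LOC115456038, 3.23 for LOC115456026, 1.28 for LOC115447244, the opposite direction, and −2.41 for LOC115454425 (edgeR adjusted p from 0.0519 to 0.733).

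Some mitochondrially encoded genes were higher after heat in LAB sham and parasitized larvae, but in sham larvae they passed the threshold only with 1 library in the fit. Those that passed encode subunits of NADH dehydrogenase, complex I of the respiratory chain. Of 12 tested mitochondrial protein-coding genes 3 passed in sham larvae, ND1, ND5 and ND6, with log2 changes of 0.97 ± 0.26, 1.02 ± 0.26 and 1.28 ± 0.36 (edgeR adjusted p = 0.0346, 0.024 and 0.0487). Without LAB_40_NP replicate 3 these were 0.76, 0.82 and 0.76 and none of the 3 passed (edgeR adjusted p = 0.0973, 0.0768 and 0.233). In parasitized larvae 4 passed, ND1, ND5, ND4L and ND6, with 1.48 ± 0.28, 1.52 ± 0.28, 1.57 ± 0.36 and 1.60 ± 0.39 (edgeR adjusted p from 0.000956 to 0.00967). All 4 passed without LAB_40_P replicate 2, which held the highest mitochondrial share of its group (edgeR adjusted p from 0.00312 to 0.0295). No such gene passed in FLD larvae for heat, where the median log2 change was 0.09 in sham and −0.17 in parasitized larvae, and none passed for the difference between populations. Of 7 subunits of this complex 3 and 4 passed, and whether they stand apart from the other mitochondrial genes was not tested. This group was chosen after the annotation was seen. Mitochondrial genes took 2.08 ± 1.13% of host counts in LAB sham and parasitized larvae together at 40 °C (n = 18) and 1.31 ± 0.474% at 25 °C (n = 19, permutation p = 0.0051, adjusted 0.0102 over 6 comparisons of shares), and 2.71 ± 1.90 against 2.65 ± 1.45% in FLD larvae (n = 20 and 20, permutation p = 0.919, adjusted 0.919). By treatment LAB sham larvae had 2.05 ± 1.27 against 1.39 ± 0.571% (n = 9 and 10, exact permutation p = 0.137) and LAB parasitized larvae 2.11 ± 1.05 against 1.22 ± 0.350% (n = 9 and 9, exact permutation p = 0.0191). Without library LAB_40_NP replicate 3, which held 5.15%, a choice made after seeing the data, the mean of LAB sham and parasitized larvae at 40 °C was 1.90 ± 0.852% (n = 17, permutation p = 0.0104) and that of sham larvae 1.67 ± 0.537% (n = 8, exact permutation p = 0.31). In LAB unmanipulated larvae the mean was lower at 40 °C, at 1.19% (n = 3, 0.544 to 2.34) against 1.72% at 25 °C (n = 4, 1.57 to 1.97). LABINFIELD means at 40 and 25 °C were 2.77 and 1.72% in sham and 1.38 and 2.49% in parasitized larvae (n = 2 each). The heat differences in share in unmanipulated and LABINFIELD larvae were not tested. In the factorial LAB groups ribosomal RNA took 26.1 ± 8.45 against 26.9 ± 8.38% of host counts at the 2 temperatures, a difference that did not pass (permutation p = 0.781, adjusted 0.919).

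FLD and LAB larvae differed in 3843 of 9372 transcripts, 2179 higher and 1664 lower in FLD larvae (edgeR). The balance of directions depended on the scaling, with 1752 higher and 2088 lower under relative log expression factors and 1685 and 2075 with DESeq2. Population and run time cannot be told apart in that comparison. Within the field run FLD larvae differed from the 8 LABINFIELD larvae in 869 transcripts, 602 higher and 267 lower (903 and 204 with DESeq2), and in 426 with only the compared groups in the fit. The laboratory population at its 2 run times, LABINFIELD minus LAB, differed in 512 transcripts, 216 higher and 296 lower, against 80 and 509 under relative log expression factors and 100 and 966 with DESeq2. Between run times no filter gave 254, the specimen number as a covariate 149 and a fit of the compared groups 992. Leaving out each LABINFIELD larva in turn gave 431 to 610 transcripts within the run, with the lowest without LABINFIELD_40_NP replicate 1. Between run times it gave 34 without that larva and 908 without LABINFIELD_40_P replicate 2. Genes that passed within the run lay in 5 runs of 3 higher genes, among them those on chromosomes 25 (13138664 to 13158879, log2 6.40 to 7.99) and 26 (8173817 to 8218720, log2 4.45 to 5.75), and in 2 runs of lower genes on chromosomes 19 (12116972 to 12758719, log2 −2.67 to −1.06) and 28 (3751209 to 3804175, log2 −2.12 to −0.67). There were 57 neighbouring pairs against 34.6 by permutation (p = 3e-04). Ribosomal RNA took 15.5 ± 8.36% of host counts in FLD (n = 40) and 26.5 ± 8.31% in LAB larvae (n = 37, permutation p = 1e-05, the smallest that the resamples can give), and mitochondrial genes took 2.68 ± 1.67 and 1.68 ± 0.930% (permutation p = 0.00157). Within the field run the 8 LABINFIELD larvae had 13 ± 14.4% of ribosomal RNA (4.85 to 47.1) and 2.09 ± 0.856% of mitochondrial counts. Neither differed from FLD larvae by its test (exact permutation p = 0.508 and 0.337, adjusted 0.508 and 0.449 over 4 comparisons). Against LAB larvae their ribosomal share was lower (exact permutation p = 0.000713, adjusted 0.00285), and their mitochondrial share missed the threshold (exact permutation p = 0.263, adjusted 0.449). Without LABINFIELD_40_P replicate 2 at 47.1% their ribosomal share was 8.13 ± 4.55% (n = 7; against FLD larvae exact permutation p = 0.0293, adjusted 0.0586). In the laboratory population the ribosomal share was 13.5 percentage points lower in the field run, and within that run FLD larvae were 2.49 points higher. These values, from 8 LABINFIELD larvae, argue against population alone as the source of the lower ribosomal share in FLD larvae. For the mitochondrial share neither comparison passed, so population and run time cannot be told apart there. The effect of parasitism at 25 °C differed between FLD and LAB larvae for 82 transcripts, 72 higher and 10 lower in FLD, among them 4 neighbouring genes on chromosome 18 (6014444 to 6065111, log2 8.59 to 11.3). That count was 34 without the 2 libraries labelled parasitized at background, 30 also without the low libraries, 25 with the specimen number as a covariate and 0 in a fit of the compared groups alone. The interaction of heat and parasitism differed for 0 transcripts (683 with an unadjusted p under 0.05, 13 with DESeq2).

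The bead injection and heat without injection were measured in few larvae. At 25 °C 59 transcripts differed between sham and unmanipulated larvae, 45 higher and 14 lower in sham larvae (n = 10 and 4; 36 and 39 under relative log expression factors, 175 and 62 with DESeq2), and at 40 °C 0 differed (n = 9 and 3; 465 with an unadjusted p under 0.05, 30 with DESeq2). At 25 °C no filter gave 16, a fit of the compared groups 39 and the specimen number as a covariate 1. Heat in unmanipulated larvae changed 72 transcripts, 59 higher and 13 lower (n = 3 and 4, edgeR with the spread of all 14 groups). With only the compared groups in the fit 745 passed, 383 higher and 362 lower, and with DESeq2 495, 234 higher and 261 lower. No filter gave 15, the stricter filter 116 and the specimen number as a covariate 7. Ribosomal RNA took 41.9 ± 6.18% of host counts in those at 40 °C (35.1 to 47.2) and 27.5 ± 6.85% in those at 25 °C (19.4 to 33.6), without overlap. Without ribosomal RNA genes 83 transcripts passed. A run of 3 genes on chromosome 14 (4170366 to 4192484) was higher by 4.34 to 5.78 in the sham comparison at 25 °C and by 4.59 to 6.31 in the heat comparison, and both use the same LAB_25_NOSHAM larvae. Leaving out each unmanipulated larva in turn gave 0 to 7 transcripts for the sham at 25 °C and 1 to 21 for heat, so these counts rest on having every larva in the fit.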

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

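The tests of a swap, of depth, of ribosomal RNA, of run time, of leaving out libraries and of calls shared with 40 °C, and the splits of LAB larvae for parasitism at 25 and 40 °C and for heat in sham larvae, were chosen after their results were seen; the score tests of the 2 libraries at background and the other splits were written before.

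The library labelled LAB_25_P replicate 8 and the library labelled LAB_40_P replicate 8 stood apart from their groups in CcBV level, at 4.32 and 4.51 on the log2(CPM + 1) scale. The lowest of the 16 other LAB parasitized libraries, LAB_25_P replicate 1, had 1479 CPM from 14 CcBV counts (95% interval 809 to 2481). The higher upper 95% limit of the 2 libraries at background was 27.1 CPM, so too few counts do not account for their level. A swap with 1 of the LAB sham libraries with counts does not either, since the highest of them had 139.8 CPM; a swap with LAB_40_NP replicate 6, which held 0 host counts, stays open. Over 149 transcripts called for parasitism at 40 °C in FLD larvae, signed by their direction there, LAB_40_P replicate 8 scored 0.179, inside the range of the 9 sham larvae (−0.379 to 0.284) and outside that of the 8 other parasitized larvae (1.77 to 2.27), and LAB_25_P replicate 8 scored 0.0913, inside the range of the 10 sham larvae (−0.346 to 0.529) and below that of the others (0.547 to 1.28). A larva in which parasitism did not take, or a wrong label from outside these groups, may account for both, and these cannot be separated with the values at hand.

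Of the CcBV genes that passed after heat, 9 of 10 in LAB and 19 of 20 in FLD larvae were lower relative to host counts. The share of ribosomal RNA in host counts does not account for the FLD difference in viral load, which was −1.12 without ribosomal RNA genes against −1.05 with them. The 2 libraries at background do not account for the LAB result, since 24 CcBV genes were called without them against 10 with them. Open explanations are a lower viral transcript level after heat, or a higher output of host mRNA per unit of viral RNA, which counts relative to the host cannot separate; with CcBV library sizes alone 12 genes were called in FLD larvae, 9 of them higher. Chance is called excluded here and below, interactions aside, where a share under 0.05 of the splits of the same libraries was as large, a share not adjusted for the number of results tested. It was excluded for the 20 genes in FLD larvae, with at most 10 in any other of the 100 splits (1 as large). For the 10 in LAB larvae 3 of 100 splits were as large, under that share, but the highest other called 24, more than the real count, which points to a structure of the LAB samples whose source was not tested. Without LAB_25_P replicate 9 the LAB count was 5.

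FLD and LAB larvae differed in 3843 transcripts. Run time alone does not account for all of it: 669 of the 3843 were also called in the same direction between FLD and LABINFIELD larvae of 1 run. Both comparisons use the same FLD larvae. Between run times 351 of the 3843 were called in the same direction. Of the 3843, 75% had the same sign within the run, and the median share of the change seen there was 0.507. The quartiles of that share were −0.00068 and 1. It varied so widely between transcripts that the median does not divide each change into population and run time. Within the run at least 431 transcripts were called whichever LABINFIELD larva was left out. Leaving out ribosomal RNA genes did not lower the count, with 3911 called. TMM factors already give a dominant gene little weight, so that count could hardly fall. It cannot tell whether whatever changed the ribosomal share also changed other transcripts. Chance was excluded across runs (3843, highest other 73), within the run (869, highest other 483) and between run times (512, highest other 3), each with 1 of 40 splits as large. The run-time count was 34 without LABINFIELD_40_NP replicate 1 and 149 with the specimen number as a covariate, so it rests on few larvae. Differences in parents, field history and handling between the populations stay open and were not tested.

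Other splits of the same libraries excluded chance for parasitism at 40 °C in LAB (463, highest other 45) and FLD larvae (155, highest other 5) and for heat in LAB parasitized larvae (406, highest other 24), each with 1 of 100 as large. For the LAB interaction (21, highest other 14) 1 of 100 was as large too. Splits for an interaction exchanged parasitized and sham labels within each temperature. Those for a difference in effect between populations exchanged FLD and LAB labels within each treatment. Both also remove the effect of parasitism or population itself, so they cannot decide whether chance accounts for an interaction or such a difference. For heat in LAB sham larvae (184) 2 of 100 were as large, also under 0.05, but the highest other called 290, more than the real count. Chance was also excluded for the sham at 25 °C (59, 1 of 40, highest other 3) and for heat in unmanipulated larvae (72, 1 of 35, highest other 0). Leaving out 1 unmanipulated larva at a time gave 0 to 7 and 1 to 21, so these counts rest on having every larva in the fit. The specimen number as a covariate gave 1 and 7. The counts alone did not exclude chance for parasitism at 25 °C in LAB (6, 8 of 100, highest other 488) and FLD larvae (17, 6 of 100, highest other 43) or for the FLD interaction (3, 11 of 100, highest other 186). In FLD larvae, however, 13 of the 17 transcripts were also lower at 40 °C in separate libraries, and 1 of 100 splits shared as many in 1 direction, the real one, with a highest other of 1, so chance does not account for these 13. In LAB larvae 1 of 6 was shared, with 7 of 100 splits as large and a highest other of 22. Chance was not excluded either for the differences between populations in parasitism at 25 °C (82, 7 of 40, highest other 300), in heat in sham larvae (31, 4 of 40, highest other 164) and in heat in parasitized larvae (4, 34 of 40, highest other 180). Where the real count was 0 every split is as large by construction, so these splits decide nothing: FLD heat in sham larvae (100 of 100, highest other 2; edgeR, 614 unadjusted, DESeq2 33), FLD heat in parasitized larvae (100 of 100, highest other 145; 806 unadjusted, DESeq2 112), the difference in interaction (40 of 40, highest other 151; 683 unadjusted, DESeq2 13), the sham at 40 °C (40 of 40, highest other 3; 465 unadjusted, DESeq2 30) and the difference in CcBV genes (100 of 100, highest other 2; 0 unadjusted, DESeq2 0). Splits that called several times the real count point to a structure of the samples, whose source was not tested; the libraries with low totals and those at background CcBV stayed in these splits.

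The interaction of heat and parasitism passed its test for 21 transcripts in LAB and 3 in FLD larvae, and the difference between populations passed for 82 transcripts for parasitism at 25 °C, 31 for heat in sham larvae and 4 for heat in parasitized larvae. For the interactions in both populations and these 3 differences chance was not excluded. The 4 LABINFIELD parasitized libraries, outside the viral comparisons, lay above the background with 7414 and 6990 CPM of CcBV at 25 °C and 2426 and 6862 CPM at 40 °C.

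In 17 cases among 105 groups of values, where chance gives about 1 in 20, a library lay far from its group. Many of these groups are of transcripts named for their large changes, which 1 library can carry. An excess over that rate is therefore not read as a result. By library these were host totals of 9450 in LAB_25_P replicate 1 and 13527808 in FLD_40_P replicate 4, ribosomal RNA of 8.33% in LAB_25_NP replicate 1 and 43.1% in FLD_40_NP replicate 7, and mitochondrial genes of 5.15% in LAB_40_NP replicate 3. On the log2(CPM + 1) scale CcBV lay at 7.04 in LAB_40_NP replicate 3 and at 0 in FLD_40_NP replicate 1, whose total was 1283 counts. On that scale, for host transcripts per 1000000 raw host counts without scaling factors and so not the CPM of the report, LOC119190794 was at 0 in LAB_25_P replicate 1, LOC115450134 at 9.99 in LAB_40_NP replicate 9 and 3.49 in LAB_40_P replicate 4, and LOC115443801 at 1.34 in LAB_25_NP replicate 1. LOC115456026 was at 0.30 in LAB_25_P replicate 7, LOC115449158 at 4.03 in LAB_40_P replicate 8, LOC115441792 at 10.79 in FLD_25_P replicate 10 and LOC115447475 at 0.89 in FLD_40_NP replicate 7.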

How the results depend on the processing

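Leaving out ribosomal RNA genes, summing transcripts per gene, leaving out the libraries at background CcBV, together or 1 at a time, leaving out the highest library of a named transcript or CcBV gene, the segment and mitochondrial shares and mitochondrial genes without doubted or highest libraries, and upper-quartile factors without the low libraries were chosen after seeing the data; the other alternatives were planned. Of the values for comparisons, 219 kept their direction and side of the threshold or stayed within 1.5 times, 71 counts moved further, 11 results came past the threshold and 7 no longer passed. Of the values for single features, segments and shares 515 kept direction and side, 20 came past the threshold, 43 no longer passed and 1 turned its sign: CcBV_30.1 in LAB larvae, 0.16 with CcBV library sizes alone. These counts leave out the removals of 1 library at a time from comparisons and the removals of the highest library below, where the LAB viral load and LOC115441792 turned their sign. Among mitochondrial genes that had not passed, ATP6 in LAB sham larvae (0.24 to −0.17 without LAB_40_NP replicate 3) also turned its sign. So did ND3 in LAB parasitized larvae (0.38 to −0.28 without LAB_40_P replicate 2). Without its highest library 7 of 29 named host transcripts no longer passed. LOC115450134 and LOC115441792 also lost most of their log2 change (−6.0 to −2.10 and 5.84 to −0.05). The others kept most of it: LOC115447475 (5.88 to 5.13) and the interactions LOC115456039 (3.72 to 3.55), LOC115449158 (−5.72 to −5.35), LOC115451181 (−3.39 to −3.13) and LOC115446822 (−2.82 to −2.63). Of 15 calls of named CcBV genes 3 ended: CcBV_18.2 (2.83 to 1.69) and CcBV_19.5 (−3.40 to −2.77) in LAB and CcBV_30.1 (−1.95 to −1.61) in FLD larvae. The causes were not tested unless stated. Upper-quartile factors with every library were not run, since the factors of the lowest libraries cannot be formed, and the gene list alternatives were not run because no list matched.

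With DESeq2 LAB larvae gave 53 transcripts for parasitism at 25 °C, 351 for heat in sham larvae, 677 for heat in parasitized larvae and 91 for the interaction. FLD larvae gave 74 and 288 for parasitism at 25 and 40 °C, 33 and 112 for heat in sham and parasitized larvae and 66 for the interaction. The differences between populations were 120 for heat in sham larvae, 24 for heat in parasitized larvae and 13 for the interaction, and it gave 1066 for run time, 237 and 30 for the sham at 25 and 40 °C, 495 for heat in unmanipulated larvae and 20 CcBV genes in LAB larvae.

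With all 14 groups in the fit, the LAB counts were 0 and 235 for parasitism at 25 and 40 °C, 110 and 171 for heat in sham and parasitized larvae and 8 for the interaction. The 0 (edgeR) stands beside 483 unadjusted in the LAB fit and 53 by DESeq2. The FLD counts in that fit were 195, 440, 67, 363 and 184 in the same order. With only the compared groups in the fit the differences between populations were 0 for parasitism at 25 °C (640 unadjusted), 18 for heat in sham and 1 for heat in parasitized larvae, run time gave 992, the within-run comparison 426, the sham at 25 °C 39 and heat in unmanipulated larvae 745. A single fit of the 4 parasitized groups gave 19 CcBV genes in LAB and 13 in FLD larvae, and CcBV library sizes alone gave 12 in FLD larvae.

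Libraries with the same replicate number did not deviate together: the mean correlation was 0.037 over 52 LAB pairs (lowest −0.232, 16 over 0.1) and 0.0325 over 60 FLD pairs (lowest −0.354, 25 over 0.1), and 4 of 37 and 5 of 40 libraries correlated best with their own number, so the numbers do not pair the larvae. With the replicate number as a block the LAB counts were 11 for parasitism at 25 °C, 45 for heat in sham larvae, 28 higher and 17 lower, 34 for the interaction and 5 CcBV genes, and FLD parasitism at 25 °C gave 10. With the block the differences between populations for parasitism at 25 °C, heat in sham and heat in parasitized larvae were 0 each, run time gave 5, the within-run comparison 559, the sham 29 at 25 °C and 1 at 40 °C, and heat in unmanipulated larvae 123. In the other comparisons the block moved counts by at most 1.5 times.

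The specimen number as a covariate gave 33 for the LAB and 1 for the FLD interaction, 25, 14 and 0 for the differences in parasitism at 25 °C, heat in sham and heat in parasitized larvae, 149 for run time, 1 for the sham at 25 °C, 7 for heat in unmanipulated larvae and 6 LAB CcBV genes. With no filter the counts were 13 for the LAB and 5 for the FLD interaction, 26 for FLD parasitism at 25 °C, 27 for FLD heat in parasitized larvae, 254 for run time, 16 for the sham at 25 °C and 15 for heat in unmanipulated larvae. The stricter filter gave 26 for FLD heat in parasitized larvae and 116 for heat in unmanipulated larvae. Relative log expression factors gave 14 for FLD heat in parasitized larvae and 7 for its difference between populations, and leaving out ribosomal RNA gave 29 for the former. The FLD viral load difference of medians was −0.92 (exact permutation p = 0.0975; 0.0173 to 0.0975 over the alternatives, adjusted 0.0346 to 0.195).

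Without the low libraries the LAB interaction gave 32 and the difference in heat in parasitized larvae 7, with or without upper-quartile factors, which gave 1 for the FLD interaction. Without the libraries at background CcBV, LAB larvae gave 30 for parasitism at 25 °C, 154 for the interaction and 24 CcBV genes, and the differences in parasitism at 25 °C and heat in parasitized larvae were 34 and 10. Without both kinds the LAB counts were 27 and 757 for parasitism at 25 and 40 °C, 166 for the interaction and 26 CcBV genes, and the differences in parasitism at 25 °C, heat in sham and heat in parasitized larvae were 30, 20 and 16. Leaving out 1 larva at a time gave 34 to 908 for run time, 431 to 610 within the run, 0 to 7 for the sham at 25 °C, 0 to 0 at 40 °C and 1 to 21 for heat in unmanipulated larvae. The LAB viral load difference ran from −1.61 to 0.18 without 1 of the 3 doubted libraries, the sign turning without LAB_40_P replicate 8, and was −0.77 without both at background and −1.10 without all 3. Depth limits the lowest libraries: 3 counts are 317 CPM in LAB_25_P replicate 1.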

Other observations

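The groups of transcripts below and the restriction of the correlation to larvae above the CcBV background were chosen after the values were seen.

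Of 215 tested long noncoding RNA genes 10 were higher and 3 lower after heat in LAB sham larvae, or 6.05% against 2.67% of all tested transcripts. In LAB parasitized larvae 1 was higher and 5 lower, or 2.79% against 5.90%. Neither an enrichment of this class nor the difference was tested. With parasitism at 40 °C 2 were higher and 8 lower of 215 in LAB larvae, and 2 higher and 5 lower of 242 in FLD larvae. Between populations, FLD minus LAB, 10 of 13 mitochondrial protein-coding genes were higher and 1 lower, and within the field run 2 of 13 were higher and 0 lower (edgeR).

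A hypothesis was that the host change follows the CcBV level across parasitized LAB larvae. At 40 °C the score over 149 transcripts and log2 CcBV CPM had a Pearson r of 0.49 (exact permutation p = 0.203) and a Spearman rho of 0.43 (exact permutation p = 0.299, adjusted 0.299 over 2 relations) in 8 larvae, with r 0.18 (exact permutation p = 0.726) without the 2 larvae farthest from the median level. At 25 °C r was −0.48 (exact permutation p = 0.269) and rho −0.50 (exact permutation p = 0.267, adjusted 0.299) in 7 larvae, and r was −0.63 (exact permutation p = 0.25) without 2. Library LAB_25_P replicate 1, with 9450 counts, was left out at 25 °C too. Neither relation passed, and with so few larvae the hypothesis stays open.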
